A study of Homo sapiens with 18 samples.

How the data were processed

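Gene and transcript tables were analysed as deposited by the authors. The raw tables hold expected counts (estimated counts) per gene symbol and per transcript, which the authors deposited without normalization. For 98.4% of genes compared, the gene values equal sums of the transcript estimates within 0.5 counts. The program that made these estimates is not given in the sources used here, which name only the human assembly hg19 and DESeq2. The deposited normalized gene table holds log2 values made by the authors, namely log2(x + 1) of counts over a factor for each library that also varied between genes. The deposited normalized transcript table was not used. Of the gene values 49.49% lay within 0.001 of a whole number. Technical libraries of a culture were summed and then rounded, because chi-square per degree of freedom between them was 1.37 to 1.49 and the correlation of their log2 values 0.992 to 0.994. This gave n = 3 cultures in each of 3 groups. The design text calls the cultures independent biological triplicates.

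Cultures of the same number in different groups were checked for shared variation. After group means were removed, cultures numbered 1 correlated at 0.52 to 0.54 with each other, same-numbered cultures 2 or 3 at 0.24 to 0.32, cultures 2 with 3 at 0.21 to 0.34, and cultures 1 with the others at -0.44 to -0.34. The number therefore set cultures 1 apart and did not tell 2 from 3. The main fit was the one fixed in advance, without a replicate block, and the fit with the culture number as a block is given beside it where a call changed or a count moved by over 1.5 times. In a principal component analysis the first 3 components held 49.4%, 19.9% and 16.2% of the variance. The first separated siCtrl from both GRHL2 siRNAs, and the remaining 2 set cultures numbered 1 apart within groups. Mitochondrial genes held 6.17% to 7.04% of the counts.

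Genes were tested with edgeR quasi-likelihood F-tests (glmQLFit, glmQLFTest) on the design ~0+group with TMM normalization and filterByExpr. Benjamini-Hochberg adjustment ran over the 13744 genes tested, and genes with an adjusted p under 0.05 were called. The contrasts were siGRHL2A against siCtrl, siGRHL2C against siCtrl, the mean of both against siCtrl, and siGRHL2A against siGRHL2C. All groups shared a single estimate of the spread. Fold changes are edgeR coefficients on the log2 scale, so they differ slightly from ratios of mean CPM. CPM came from the edgeR function cpm with TMM-scaled library sizes. Transcripts were tested in the same way, and relative transcript use with edgeR diffSpliceDGE and gene-level Simes p-values for genes with at least 2 transcripts past the filter.

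The 20 gene lists and the list of ESRP splicing targets were fixed before the data were examined, from general knowledge of these pathways. List tests were camera with a preset correlation of 0.01 (main), camera with an estimated correlation, and fry, adjusted over the 20 lists. Camera compares a list with the other genes, and fry tests it against no change. List p-values with the block, without a culture or on genes without 7-mers used the preset correlation. Some genes sit in more than 1 list: 6 of the oestrogen receptor targets, 4 of the luminal transcription factors, 4 of the growth factor list, 3 of the mesenchymal list, 2 of the basal list, 2 of the fibroblast and immune list, and 1 each of the epithelial regulator, keratin, secretory and TGF-beta lists were also in another. For list members, calls were also made with p adjusted over the list alone.

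Genes named in the text followed a rule fixed before the data were examined. Named were the GRHL family and the FOXA1 group whatever their values. Also named were the 10 largest rises and 10 largest falls in the mean contrast among genes called with the same sign with each siRNA. These needed a mean CPM of at least 5 and control cultures that did not overlap the 6 knockdown cultures. From each list up to 4 members with the smallest adjusted p in the mean contrast were eligible. Between the siRNAs the 5 largest differences each way at a mean CPM of at least 5 were named, and of the ESRP targets those called for use. Any other gene is said to have been picked after its values were seen.

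The siRNA sequences are not given in the sources used here. Off-target effects were therefore searched for without them, by a regression of the fold changes of each siRNA against the mean of the others on the presence of each of 16232 7-mers in the 3′ UTRs of 13137 genes. Length, GC content and expression level were covariates. Each 7-mer had to occur in at least 50 genes, and the Bonferroni bound was an absolute t of 4.665. The 7-mers of an siRNA are the leading 7-mer and its overlapping runner-up: GCAGTAC and CAGTACA for siCtrl, TGTGTTA and ATGTGTT for siGRHL2A, ATATGTA and TATGTAA for siGRHL2C. Of the 112 named genes 14, 26 and 35 carried them, 58 carried none and 1 was not searched. Of all genes scanned 10.2%, 25.4% and 24.8% carried them, so carrying one does not by itself mark a gene as a target. The 3′ UTRs, the exon overlaps between neighbouring genes and the transcript names came from GENCODE v29 on GRCh38, whereas the deposited tables were made on hg19, so no coordinates are given. Of the 94385 transcripts 93372 were matched to that annotation, and 98.4% of genes compared had transcript sums within 0.5 counts of the gene table.

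The methods were tried on simulated data first. Of planted 1.5-fold changes 50.7% to 68.7% were recovered, of 2-fold changes 82.1% to 91%, and of 4-fold changes 97% to 100%, with 4 to 18 false calls. A list shifted by 0.4 was found and no other list was called. The usage test recovered 190 of 200 planted genes with 92 others, and called 34 to 48 genes without any change. The limma ratio test recovered 187 with 14 others. The transcript test recovered 85.5% with 16 others. The 7-mer search found 20 of 20 planted 7-mers, and 1 passed after the fold changes were shuffled.

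Alternatives fixed before the data were examined were RLE and upper-quartile factors, no count filter, a CPM filter, DESeq2, limma on the deposited log2 values, either technical library alone, all 18 libraries as independent, fits on the 2 groups compared, the replicate block, 6 knockdown against 3 control cultures, each culture left out, an adjusted p under 0.01, a test against a log2 fold change of 1, and the other list tests. The limma run used the deposited log2 values without a second logarithm. Added later were fits without the cultures numbered 1, fits on genes with none of the siRNA 7-mers, and a limma test of transcript ratios with a pseudocount of 0.5. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.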

Results

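Polyadenylated RNA was sequenced from TAMR cells, a breast cancer line derived from MCF7 that is resistant to 4-hydroxytamoxifen, the active form of the oestrogen receptor antagonist tamoxifen. The cells were harvested 72 hours after transfection with a control siRNA (siCtrl) or with 1 of 2 siRNAs against GRHL2, named siGRHL2A and siGRHL2C. GRHL2 is a grainyhead-like transcription factor of epithelial cells. Each siRNA had 3 cultures and each culture 2 technical libraries, 18 libraries in all. The libraries held 11725674 to 16348555 estimated counts. The 9 cultures held 23566644 to 32525468 after the technical libraries of a culture were added up. Of the 20527 genes in the table, 13744 had enough counts to be tested and 2699 had no count in any library. Levels are counts scaled by library size (CPM), given as mean ± SD over n = 3 cultures where an SD is printed, changes are log2 fold changes, and p-values are edgeR values adjusted over all genes tested. Cultures numbered 1 stood apart from those numbered 2 and 3. Chi-square per degree of freedom between 2 cultures of a group was 12.7 to 18.8 for pairs with number 1 and 1.95 to 3.25 for pairs without it, against 1.37 to 1.49 between technical libraries. Fits without all cultures numbered 1 rest on the closer pairs of cultures 2 and 3. Their p-values may therefore understate the spread between cultures.

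How far each siRNA lowered its target was asked first. GRHL2 fell with both siRNAs and stood lower with siGRHL2C than with siGRHL2A. Its level was 287 ± 6.32 CPM with siCtrl, 209 ± 10.9 with siGRHL2A and 83.3 ± 14.6 with siGRHL2C, which left 72.8% and 29% of the control level. The log2 fold change was -0.46 with siGRHL2A (SE 0.11, adjusted p = 0.00714) and -1.79 with siGRHL2C (SE 0.11, adjusted p = 2.65e-06). In the direct test the siRNAs differed by 1.33 (SE 0.11, adjusted p = 4.73e-05), and all 3 cultures of each siRNA lay below all 3 control cultures. The paralog GRHL1 fell with siGRHL2A, from 62.7 ± 2.17 to 36.9 ± 4.59 CPM (log2 fold change -0.77, adjusted p = 0.000153). With siGRHL2C it fell less, to 52.0 ± 2.78 CPM (-0.27, adjusted p = 0.0287), and the direct test put GRHL1 lower with siGRHL2A (-0.49, adjusted p = 0.0031). In its 3′ UTR GRHL1 carried a 7-base sequence that marked genes lower with siGRHL2C (a 7-mer of that siRNA) and a 7-mer of siCtrl. The siGRHL2C call for GRHL1 was lost without siCtrl culture 2 (adjusted p = 0.0859), siCtrl culture 3 (0.0582), siGRHL2C culture 1 (0.0882) or siGRHL2C culture 2 (0.0593). GRHL3, the remaining paralog, measured 29.2 ± 2.34, 34.0 ± 1.8 and 31.9 ± 2.26 CPM and did not pass the test for the mean of both siRNAs (0.18, adjusted p = 0.0647). It passed with culture number as a replicate block (adjusted p = 0.0429), and without siCtrl culture 1 (0.0199), without siGRHL2C culture 1 (0.0342) or without all cultures numbered 1 (0.000523). With siGRHL2A alone GRHL3 was at an adjusted p of 0.054, and at 0.0344 with the block.

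The series title links GRHL2 to FOXA1, a pioneer factor of luminal cells, and the FOXA1 group fixed for this question went in both directions. LYPD3, a membrane-anchored surface protein, fell from 165 ± 4.47 CPM to 85.2 ± 9.2 with siGRHL2A and 62.3 ± 5.55 with siGRHL2C (log2 fold changes -0.96 and -1.41, adjusted p = 3.66e-05 and 3.18e-06). AGR2, a protein disulfide isomerase of the secretory pathway, fell to 33.4 ± 2.43 and 52.9 ± 3.19 CPM (-1.95 and -1.29, adjusted p = 0.0007 and 0.00469). AGR2 varied within the controls, with 210 CPM in siCtrl culture 1 against 84.5 and 94.0 in the others, and carried a 7-mer of siGRHL2A. Without siCtrl culture 1 its change with siGRHL2C was -0.76 (adjusted p = 0.000135). FOXA1 itself rose, from 258 ± 16.9 to 292 ± 5.4 and 339 ± 4.25 CPM (0.18 and 0.39, adjusted p = 0.0267 and 0.000311). The siGRHL2A call for FOXA1 was lost without siCtrl culture 2 (adjusted p = 0.0985), siCtrl culture 3 (0.109), siGRHL2A culture 2 (0.083) or siGRHL2A culture 3 (0.0781). ESR1, the gene of oestrogen receptor alpha, measured 241 ± 5.27, 268 ± 19.8 and 274 ± 24.3 CPM and did not pass for the mean of both siRNAs (0.17, adjusted p = 0.0571). It passed with the replicate block (0.0147) and without siGRHL2A culture 1 (0.0332), siGRHL2C culture 1 (0.0213) or all cultures numbered 1 (0.000192). The last value comes from the closer cultures 2 and 3 alone. With siGRHL2A and siGRHL2C alone ESR1, which carried 7-mers of both, was at 0.139 and 0.0649, and at 0.0477 and 0.0172 with the block.

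**Figure D1:**
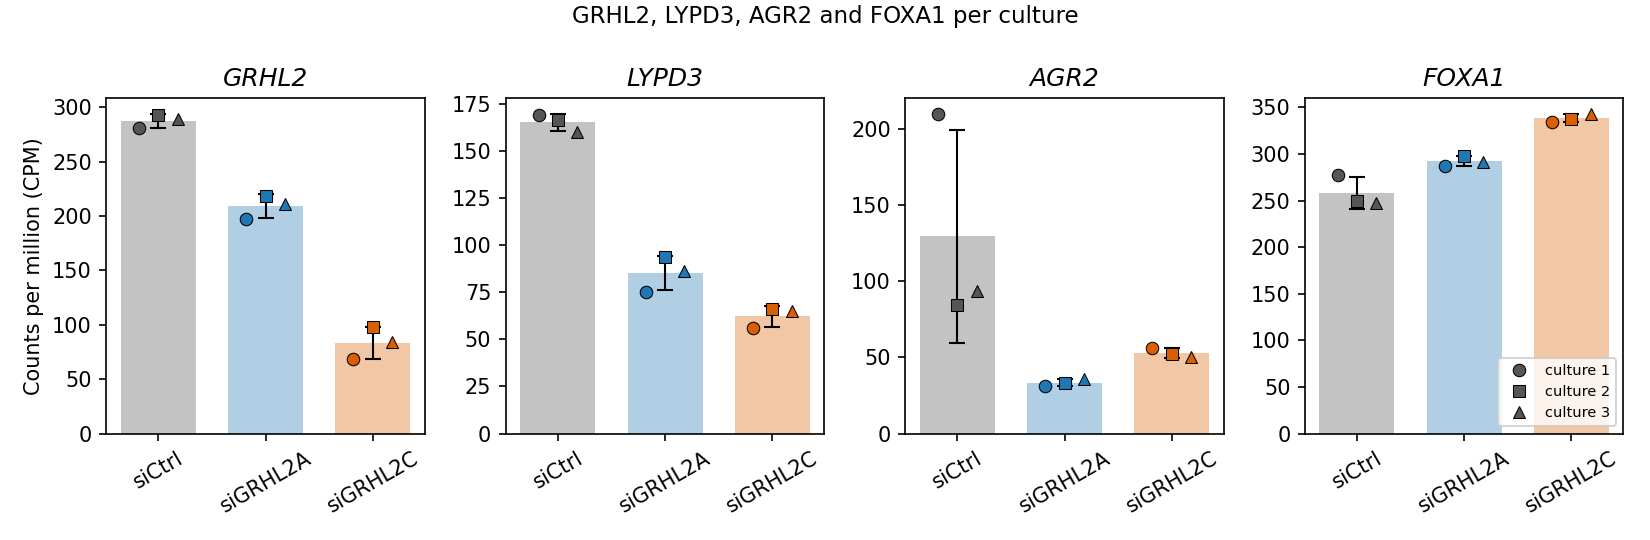
Level of GRHL2, LYPD3, AGR2 and FOXA1 in CPM on linear axes, for siCtrl, siGRHL2A and siGRHL2C; bars are the mean of 3 cultures, error bars the SD and points the cultures numbered 1 to 3. GRHL2 steps down from 287 to 209 and 83.3 CPM, LYPD3 and AGR2 lie below the control with both siRNAs, and FOXA1 lies above it.

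What the GRHL2 siRNAs do to the transcriptome was tested as the mean of both siRNA effects against siCtrl. The labels pool both siRNAs in a single GRHL2 group. This contrast compares siRNAs, so it can hold off-target effects of any siRNA used beside those of GRHL2 depletion. The largest named rises were mostly in genes barely expressed in control cells, and the largest named falls in genes the control cells expressed at 12.7 to 166 CPM. Named genes had to average at least 5 CPM over all cultures. A gene low in control cells could therefore not be among the falls, so the rule itself sets part of this contrast. In total 7032 of 13744 genes changed (51.2%), 3424 of them higher and 3608 lower, and 1242 changed at least 2-fold (662 higher and 580 lower). The genes named next passed in each siRNA alone with the same sign, and their 3 control cultures did not overlap the 6 knockdown cultures, as held for 3555 genes. Without the cultures numbered 1 the number of genes changed in the mean of both siRNAs was 8789, against 7032 with all cultures.

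TIMP3, an inhibitor of matrix metalloproteinases, rose from 14.7 ± 1.44 CPM to 265 ± 150 with siGRHL2A and 757 ± 337 with siGRHL2C (mean log2 fold change 4.93, adjusted p = 1.78e-05). SFT2D3 rose from 0.0654 CPM, with 1, 5 and 0 counts in the control cultures, to 22.31 ± 0.522 and 19.99 ± 2.42 CPM. All of its exon bases (100%) lay within exons of WDR33 on the opposite strand, so its counts may not all be its own transcript. ADAM12, a metalloprotease (3.38), the airway secretory genes BPIFB1 (3.32) and SCGB1A1 (2.77), the interferon-induced OAS2 (3.31) and the basal keratin gene KRT17 (2.53) rose too, each from under 2 CPM in control cells. Among genes expressed above that level, CHPF, a chondroitin-polymerising factor, rose from 31.7 ± 4.09 to 173 ± 4.24 and 187 ± 9.52 CPM, and YWHAH, a 14-3-3 protein, from 37.2 ± 5.48 to 211 ± 15.7 and 205 ± 11.9 CPM. PXYLP1, a xylose phosphatase of proteoglycan synthesis, rose by 2.46 on the log2 scale. CHPF, YWHAH and PXYLP1 carried a 7-mer of siCtrl, ADAM12 those of all 3 siRNAs, TIMP3 and OAS2 a 7-mer of siGRHL2C, and SFT2D3, BPIFB1, SCGB1A1 and KRT17 none of the 3 siRNAs' 7-mers. For BPIFB1 the call with siGRHL2A alone was lost without siCtrl culture 2 (adjusted p = 0.0823), siCtrl culture 3 (0.0868), siGRHL2A culture 1 (0.0838) or siGRHL2A culture 2 (0.0501). BPIFB1 measured 32.3 CPM in siGRHL2C culture 1 against 8.69 and 7.98 in the others.

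CRISP3, a secreted cysteine-rich protein, fell from 166 ± 32.2 CPM to 21.2 ± 10.2 with siGRHL2A and 10.1 ± 5.99 with siGRHL2C (mean log2 fold change -3.51, adjusted p = 7.38e-05). NRP2, a co-receptor for semaphorins and VEGF, fell from 20.7 ± 2.55 to 1.51 ± 0.53 and 2.66 ± 0.618 CPM (-3.37, adjusted p = 1.41e-06). BNIPL fell by 3.28, SYT16 by 3.17, the microtubule-severing FIGN by 3.01 and the prostatic acid phosphatase gene ACPP by 2.89 on the log2 scale. The growth factor gene BMP5 (-2.78), the adhesion receptor ADGRF4 (-2.73), the uroplakin UPK3B (-2.71) and SH3TC2 (-2.67) completed the 10 largest falls. NRP2 carried a 7-mer of siGRHL2A, SYT16 and ADGRF4 carried 7-mers of siGRHL2C, FIGN, ACPP and SH3TC2 carried those of both, and CRISP3, BNIPL, BMP5 and UPK3B carried none.

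Most genes of the hypoxia and glycolysis list and of the interferon response list rose with both siRNAs, although neither list passed with an estimated correlation. In the hypoxia and glycolysis list 23 of 30 measured genes rose and 2 fell (23 and 2 when adjusted over the list alone), and the list was higher than other genes (camera adjusted p = 6.91e-09; adjusted p = 0.253 with an estimated correlation). PFKFB3, which makes the glycolytic activator fructose 2,6-bisphosphate, rose from 35.4 ± 3.33 to 80.1 ± 6.08 and 88.3 ± 2.27 CPM. The pyruvate dehydrogenase kinase PDK1 (1.31), the lipase inhibitor ANGPTL4 (1.71) and the angiogenic factor VEGFA (1.18) rose as well. PFKFB3 and VEGFA carried a 7-mer of siGRHL2C and PDK1 those of all 3 siRNAs. The list's median was 0.47 in its 16 members without any of these 7-mers and 0.44 in its 14 with them. In the interferon response list 26 of 36 genes rose and 2 fell (26 and 2 adjusted over the list alone), with camera adjusted p = 4.01e-05 and adjusted p = 0.622 with an estimated correlation. ISG15, a ubiquitin-like modifier, rose from 11.7 ± 0.354 to 40.6 ± 8.7 and 35.8 ± 3.39 CPM, and the signal transducer IRF9 from 7.32 ± 0.25 to 21.7 ± 4.44 and 17.1 ± 1.41 CPM. IFITM1 rose by 2.15, although 32.5% of its exon bases are shared with IFITM2. Antigen presentation went both ways, with 5 of 19 genes higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.854): HLA-E rose (0.35), HLA-B rose (0.44) and the peptide trimmer ERAP1, with a 7-mer of siGRHL2A, fell (-0.48). Among NF-kappaB and inflammatory genes 5 of 16 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.279, or 0.0405 with the replicate block; adjusted p = 0.817 with an estimated correlation and no block). Examples were SOD2, mitochondrial superoxide dismutase (0.49), and TNF, which rose from 0.287 ± 0.255 to 2.17 ± 1.76 and 3.05 ± 2.38 CPM. TNF was highest in the cultures numbered 1, with 0.58, 4.18 and 5.81 CPM in siCtrl, siGRHL2A and siGRHL2C against 0.12 to 0.16, 0.94 to 1.39 and 1.64 to 1.71 in the others.

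Mitotic genes were lower in the mean of both siRNAs, and this came from siGRHL2C, since the G2/M list had a median of 0.05 with siGRHL2A and -0.86 with siGRHL2C. In the G2/M and mitosis list 29 of 40 genes fell and 3 rose (30 and 3 adjusted over the list alone; camera adjusted p = 0.0017; adjusted p = 0.817 with an estimated correlation). TOP2A, the mitotic topoisomerase, measured 311 ± 47.4 CPM with siCtrl, 306 ± 13.3 with siGRHL2A and 110 ± 15.5 with siGRHL2C. The centromere histone gene CENPA (-1.06) and the spindle gene DLGAP5 (-0.73) fell, while PRC1, a spindle midzone protein that carried a 7-mer of siCtrl, rose (1.20). CENPA carried a 7-mer of siGRHL2C. Of the G1/S and replication genes 14 of 40 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.216, and 0.0249 without siCtrl culture 2; adjusted p = 0.817 with an estimated correlation over all cultures). The median of this list was 0.08 with siGRHL2A and -0.47 with siGRHL2C. In the mean RFC5, a clamp loader subunit, fell by 0.67 and the ribonucleotide reductase subunit RRM1 by 0.45 on the log2 scale, and both fell with each siRNA. The flap endonuclease FEN1, with 7-mers of both GRHL2 siRNAs, fell by 0.67 and DTL by 0.56 in the mean. With siGRHL2A alone FEN1 (0.004, adjusted p = 0.981) and DTL (-0.25, adjusted p = 0.128) did not pass. With siGRHL2C they fell by 1.34 and 0.87. In the p53 target and apoptosis list 6 of 28 genes rose and 6 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.297). BCL2L11, which encodes the pro-apoptotic BIM and carried a 7-mer of siGRHL2C, rose (0.84), as did AEN (0.76) and RRM2B (0.60, with a 7-mer of siCtrl), whereas the executioner caspase gene CASP3 fell (-0.62). Ribosomal protein genes were higher in 9 of 31 cases and lower in none (8 and 0 adjusted over the list alone; camera adjusted p = 0.274), and the rises were small, such as RPLP2 at 0.21, RPL35 at 0.24, RPL22, with a 7-mer of siGRHL2A, at 0.18 and RPS16 at 0.26.

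Epithelial structure genes changed in both directions, and none of their lists differed from other genes by camera. Fry, which tests a list against no change, called cell junctions lower (adjusted p = 0.0378), epithelial regulators lower (0.00187) and keratins higher (0.0378). Of the cell junction and adhesion genes 11 of 39 rose and 17 fell (12 and 17 adjusted over the list alone; camera adjusted p = 0.501). The desmosomal linker DSP rose from 319 ± 23 to 704 ± 27.6 and 923 ± 43.7 CPM, and plakophilin PKP3 from 129 ± 3.71 to 215 ± 2.09 and 216 ± 15.4 CPM. NECTIN4, an adherens junction receptor, fell from 106 ± 8.53 to 61.1 ± 3.19 and 43.5 ± 1.51 CPM, and PERP, a desmosome-associated membrane protein, by 0.99 on the log2 scale. DSP carried a 7-mer of siCtrl and NECTIN4 a 7-mer of siGRHL2C. Among epithelial regulators and proteases 9 of 35 rose and 11 fell (9 and 11 adjusted over the list alone; camera adjusted p = 0.29). ESRP1, the epithelial splicing regulator, fell from 365 ± 10.6 to 264 ± 10.2 and 260 ± 6.98 CPM (-0.48) and carried a 7-mer of siGRHL2C. CDS1 (-0.81) and EXPH5 (-1.01), both with 7-mers of both GRHL2 siRNAs, fell, and the mucin gene MUC1 rose from 443 ± 53.6 to 814 ± 27.2 and 708 ± 30.5 CPM. In the keratin and luminal structure list 4 of 10 genes rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.337). KRT19 rose by 0.42 and KRT81 by 2.18, and KRT80, which carried a 7-mer of siCtrl, fell by 0.48 on the log2 scale. Keratin genes such as KRT17 and KRT81 have close paralogs, and how their shared reads were assigned is not known here.

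Basal, mesenchymal and signalling genes followed. Of the basal and myoepithelial markers 5 of 13 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.279), with a median of -0.06 but a mean of 0.47. EGFR rose from 62.4 ± 5.92 to 97.7 ± 2.16 and 103 ± 11.8 CPM. The smooth muscle actin gene ACTA2 rose in the mean (0.52) with 8.45, 8.67 and 17.1 CPM in the 3 groups. In the mesenchymal and EMT list 13 of 26 genes rose and 6 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.0348; adjusted p = 0.622 with an estimated correlation). This call was lost without siCtrl culture 1 (0.0607), siGRHL2A culture 2 (0.0508) or siGRHL2A culture 3 (0.0585). TGFB1, the growth factor TGF-beta 1, rose from 22.8 ± 2.92 to 92.9 ± 1.58 and 77.3 ± 2.25 CPM, and the collagen cross-linking oxidase LOXL2 from 10.1 ± 1.3 to 36.4 ± 7.16 and 53.7 ± 7.11 CPM. The collagen VI genes COL6A2 (1.40) and COL6A1 (1.02) and the matrix protein gene SPARC (3.12) rose, the last from 0.00 to 0.22 CPM in the control cultures. EGFR, ACTA2, SPARC and COL6A1 carried a 7-mer of siGRHL2A. Members that fell included the intermediate filament gene VIM (-0.65) and the EMT transcription factor ZEB1 (-1.60), picked after their values were seen. Of the growth factor receptors and MAPK targets 13 of 32 rose and 7 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.279, fry higher at 0.00156). FGFR1 rose from 22.5 ± 6.19 to 60.3 ± 2.03 and 99.1 ± 4.76 CPM while FGFR2 fell from 24.1 ± 2.57 to 13.2 ± 0.668 and 8.91 ± 0.268 CPM. The receptor ERBB4 fell (-1.67) and the AP-1 subunit JUN rose (0.87). FGFR2 and ERBB4 carried 7-mers of both GRHL2 siRNAs. In the TGF-beta, BMP and Hippo list 6 of 23 rose and 9 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.528). The Hippo-YAP target CYR61 fell from 25.4 ± 7.47 to 9.93 ± 1.69 and 5.16 ± 0.458 CPM, the angiomotins AMOTL1 (-1.77) and AMOTL2 (-0.81) fell, and PMEPA1 rose (0.79). AMOTL1 and AMOTL2 carried a 7-mer of siGRHL2A, AMOTL1 and PMEPA1 a 7-mer of siCtrl, and PMEPA1 a 7-mer of siGRHL2C.

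The hormone-related, luminal and metabolic lists did not differ from other genes by camera. Fry called luminal transcription factors higher (adjusted p = 0.00232) and fibroblast and immune markers lower (0.00187), and not the oestrogen receptor targets (0.743), secretory genes (0.83) or cholesterol synthesis genes (0.0642). Of the oestrogen receptor targets 14 of 44 rose and 17 fell (14 and 17 adjusted over the list alone; camera adjusted p = 0.854), with a median of 0.01 and a mean of -0.04. ADCY9, an adenylate cyclase, rose from 12.2 ± 1.09 to 34.1 ± 3.28 and 38.0 ± 2.19 CPM, and MYC from 90.9 ± 4.28 to 151 ± 6.7 and 165 ± 11.5 CPM. The receptor co-regulator NRIP1 fell from 82.7 ± 9.4 to 29.9 ± 2.33 and 42.6 ± 2.5 CPM, and the scaffold gene PDZK1 from 27.0 ± 1.08 to 5.70 ± 0.917 and 12.8 ± 1.98 CPM. ADCY9 and NRIP1 carried a 7-mer of siGRHL2C. In the luminal transcription factor list 11 of 31 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.279, and 0.00157 with the preset correlation among genes without any siRNA 7-mer; adjusted p = 0.622 with an estimated correlation over all genes). CREB3L1, a membrane-bound factor of secretory cells, rose from 20.4 ± 0.493 to 101 ± 17.6 and 122 ± 11.3 CPM. SPDEF (0.77) and TFAP2A (0.42) rose and KLF4, with 7-mers of both GRHL2 siRNAs, fell (-1.09). In the secretory and unfolded protein response list 5 of 23 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.854), with a median of -0.02 and a mean of 0.07. TRIB3, a stress-induced pseudokinase, rose from 37.8 ± 4.38 to 90.3 ± 21.8 and 132 ± 22.3 CPM, HERPUD1 rose (0.40) and EDEM1 fell (-0.57). Among cholesterol and fatty acid synthesis genes 12 of 30 rose and 5 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.279). The sterol enzyme MSMO1, with 7-mers of siCtrl and siGRHL2C, rose (0.75), and the elongase ELOVL6 (-1.12), the sterol desaturase SC5D (-0.55) and the sterol sensor partner INSIG1 (-0.62) fell. ELOVL6 and SC5D carried a 7-mer of siGRHL2C and INSIG1 a 7-mer of siGRHL2A. Of 19 fibroblast and immune markers 5 were measured, none rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.279), namely the endothelial gene VWF, from 30.1 ± 4.99 to 8.60 ± 1.27 and 3.85 ± 0.5 CPM. With the replicate block the collagen gene COL1A1 (0.20, adjusted p = 0.0329, and 0.073 without the block) and the cadherin gene CDH5 (0.87, adjusted p = 0.0154, and 0.176 without it) also passed as higher. COL1A1 passed without siGRHL2A culture 1 (0.0428), siGRHL2C culture 1 (0.0271) or all cultures numbered 1 (0.00172), and CDH5 without siCtrl culture 1 (1.53, adjusted p = 0.0252) or all cultures numbered 1 (0.000371). The antigen presentation list had a median of 0.05 and a mean of -0.05, and these sign differences concern lists that did not pass.

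**Figure D2:**
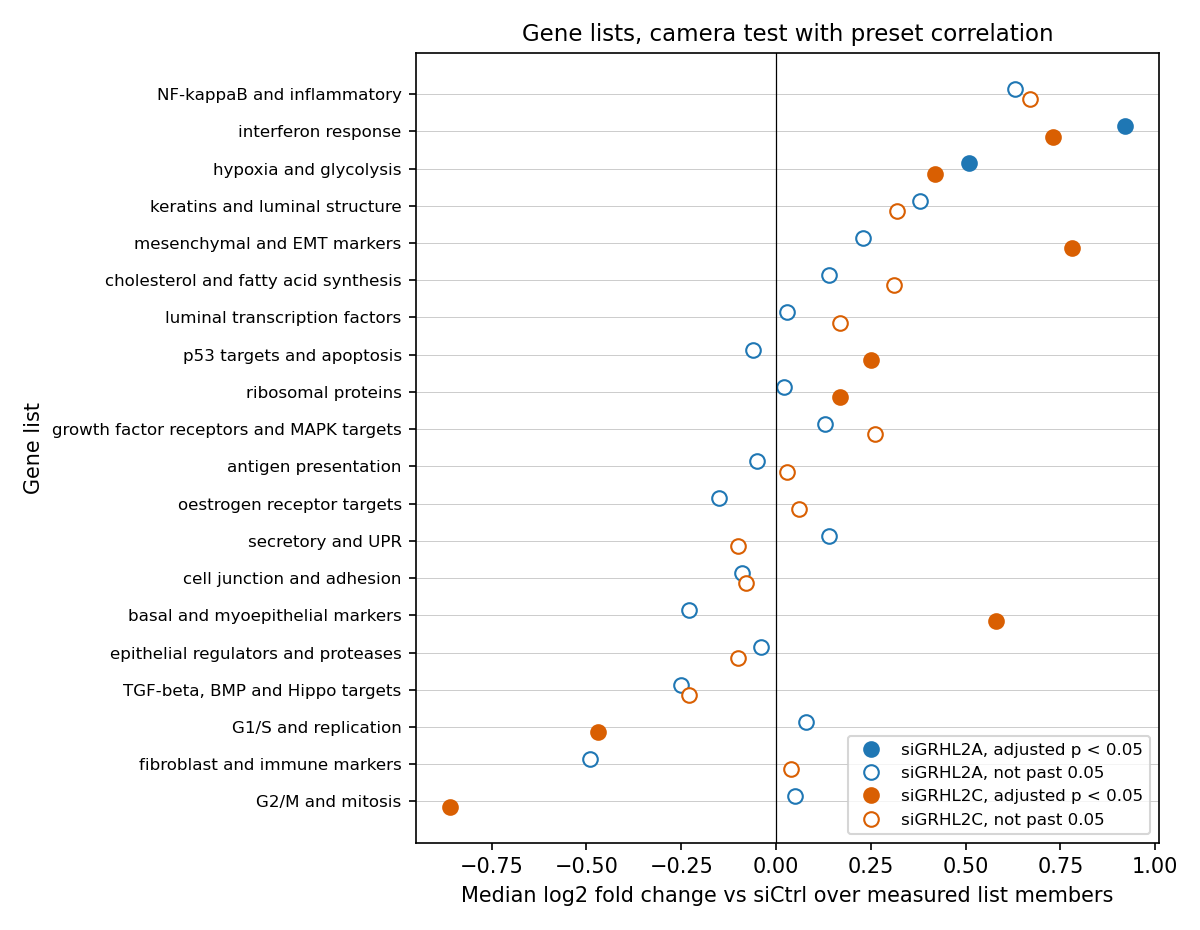
Median log2 fold change of each fixed gene list with siGRHL2A and with siGRHL2C against siCtrl on a linear axis; filled points passed camera at an adjusted p under 0.05 with the preset correlation, which none did with an estimated correlation. The interferon and hypoxia lists lie above 0 with both siRNAs, and the G2/M list lies at 0.05 with siGRHL2A and -0.86 with siGRHL2C.

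Each siRNA was then compared with siCtrl on its own. With siGRHL2A 5952 genes changed (43.3%), 3022 higher and 2930 lower, of which 1094 changed at least 2-fold. Interferon genes (24 of 36 higher and 1 lower, 24 and 1 adjusted over the list alone) and hypoxia and glycolysis genes (22 of 30 higher and 2 lower, 23 and 2 adjusted over the list alone) were the lists that passed. Their camera adjusted p were 5.14e-07 and 1.86e-09. With an estimated correlation these became adjusted p = 0.962 with an estimated correlation for interferon and adjusted p = 0.213 with an estimated correlation for hypoxia. The G1/S list (8 of 40 higher and 2 lower, 5 and 1 adjusted over the list alone, camera adjusted p = 0.602) and the G2/M list (6 of 40 higher and 1 lower, 5 and 0 adjusted over the list alone, camera adjusted p = 0.558) passed without siCtrl culture 1 (0.0443 and 0.0212) with the preset correlation. With all cultures both had adjusted p = 0.962 with an estimated correlation. The basal list had a median of -0.23, a mean of 0.05 and an upward but uncalled test.

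With siGRHL2C 7032 genes changed (51.2%), 3495 higher and 3537 lower, of which 1636 changed at least 2-fold. Mitotic genes fell as a group: 36 of 40 G2/M genes fell and 1 rose (37 and 1 adjusted over the list alone), with camera adjusted p = 2.39e-13 and adjusted p = 0.566 with an estimated correlation. Of the G1/S genes 29 of 40 fell and 1 rose (30 and 1 adjusted over the list alone; camera adjusted p = 5.62e-05; adjusted p = 0.582 with an estimated correlation). Mesenchymal genes were higher, with 13 of 26 up and 5 down (13 and 5 adjusted over the list alone; camera adjusted p = 0.000705; adjusted p = 0.553 with an estimated correlation). Interferon (24 of 36 up, 2 down; 25 and 2 adjusted over the list alone) and hypoxia genes (21 of 30 up, 2 down; 21 and 2 adjusted over the list alone) passed at 0.00158 and 3.32e-07. Theirs were adjusted p = 0.566 with an estimated correlation and adjusted p = 0.425 with an estimated correlation. Basal markers (5 of 13 up, 0 down; 5 and 0 adjusted over the list alone) passed at 0.0274 (adjusted p = 0.566 with an estimated correlation) but not without siCtrl culture 1 (0.0537). The p53 list (14 of 28 up, 6 down; 14 and 6 adjusted over the list alone) passed at 0.0361 (adjusted p = 0.566 with an estimated correlation) but not without siCtrl culture 2 (0.0611) or among genes free of siRNA 7-mers (0.114). Ribosomal protein genes (16 of 31 up, 0 down; 17 and 0 adjusted over the list alone) passed at 0.0228 (adjusted p = 0.677 with an estimated correlation) but not without siCtrl culture 1 (0.0537) or siGRHL2C culture 1 (0.0848). The replicate block added keratins (0.0249), luminal factors (0.0434), NF-kappaB (0.0361), cholesterol synthesis (0.0434) and growth factor receptors (0.0403), all with the preset correlation. In the fit without the block these lists had adjusted p = 0.566, 0.553, 0.81, 0.582 and 0.553 with an estimated correlation, which was not run with the block. Cholesterol synthesis, at 0.0794 without the block, also passed without siGRHL2C culture 2 (0.0431) or 3 (0.0306). The secretory list had a median of -0.1 and a mean of 0.09, the antigen presentation list 0.03 and -0.01, and the fibroblast and immune list 0.04 and -0.27, all uncalled.

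Changes shared by both siRNAs are less open to the off-target effects of either GRHL2 siRNA alone. With the same sign 4146 genes changed with both siRNAs, 2151 higher and 1995 lower, where independent calls would give 768 and 754, while 187 changed in opposite directions. CREB3L1 (2.31 with siGRHL2A and 2.58 with siGRHL2C) and TGFB1 (2.02 and 1.76) were among the shared rises, and VWF (-1.80 and -2.96), AMOTL1 (-1.71 and -1.83) and ERBB4 (-1.66 and -1.67) among the shared falls. The median absolute change of the shared genes was 0.58 with siGRHL2A and 0.64 with siGRHL2C, and 57.9% of them changed more with siGRHL2C. Both contrasts share the same 3 control cultures, which alone makes their fold changes correlate. In 20 simulations of unchanged groups the correlation across genes averaged 0.5 (highest 0.537) against 0.749 observed, and no gene was called with both siRNAs. Genes are not independent replicates, and the controls are too few to be divided between the contrasts.

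**Figure D3:**
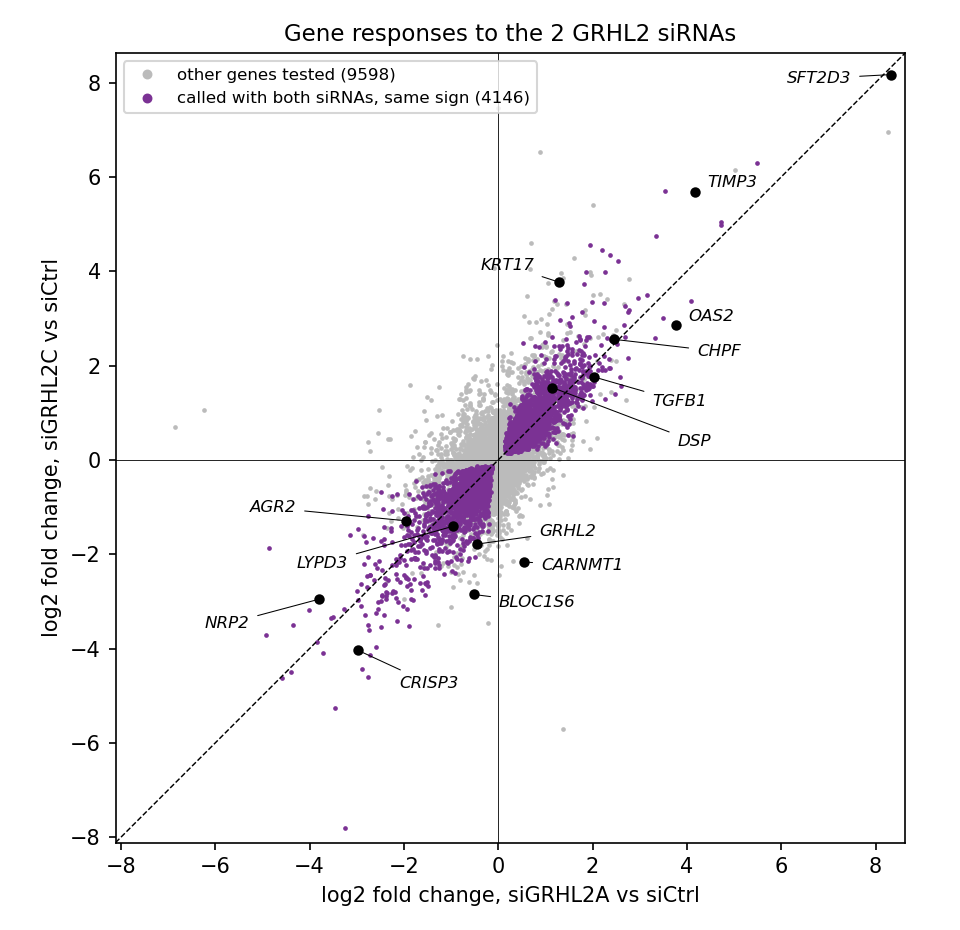
Log2 fold change of each tested gene with siGRHL2C (vertical) against siGRHL2A (horizontal), both against siCtrl on linear axes; the 4146 genes called with both siRNAs and the same sign are marked apart from the others. GRHL2 lies lower on the siGRHL2C axis (-1.79) than on the siGRHL2A axis (-0.46).

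The siRNAs were also compared with each other. Cell cycle genes were mostly lower with siGRHL2C, and some basal, mesenchymal and p53-linked genes were higher with it. No list passed here with an estimated correlation, as the values beside each list show. In total 4162 genes differed (30.3%), 2152 higher with siGRHL2A and 2010 higher with siGRHL2C, and 537 differed at least 2-fold. All 40 G2/M genes were higher with siGRHL2A (40 and 0 lower adjusted over the list alone; camera adjusted p = 1.85e-39; adjusted p = 0.343 with an estimated correlation), TOP2A by 1.48 and CENPA by 1.64. Of the G1/S genes 34 of 40 were higher with siGRHL2A and none lower (36 and 1 adjusted over the list alone; camera adjusted p = 1.95e-14; adjusted p = 0.473 with an estimated correlation), FEN1 by 1.34. The G2/M difference had a median of 0.9 in the 28 genes without any siRNA 7-mer and 0.98 in the 12 with them. With the replicate block 6333 genes differed between the siRNAs, and 6363 without the cultures numbered 1.

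Basal markers were lower with siGRHL2A than with siGRHL2C in 7 of 13 genes and higher in none (8 and 0 adjusted over the list alone; camera adjusted p = 0.00096; adjusted p = 0.49 with an estimated correlation), among them ACTA2 (-0.98). Mesenchymal genes were lower in 12 of 26 and higher in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000406; adjusted p = 0.473 with an estimated correlation), such as COL6A2 (-0.67) and COL6A1 (-0.70). The p53 list was lower in 15 of 28 and higher in 3 (16 and 3 adjusted over the list alone; camera adjusted p = 0.000391; adjusted p = 0.473 with an estimated correlation), including RRM2B (-0.49). Oestrogen receptor targets were lower in 14 of 44 and higher in 3 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00237; adjusted p = 0.343 with an estimated correlation), PDZK1 by -1.17. Ribosomal protein genes were lower in 12 of 31 (14 adjusted over the list alone; camera adjusted p = 0.00096; adjusted p = 0.752 with an estimated correlation). Cholesterol and fatty acid synthesis genes were lower in 11 of 30 and higher in 4 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0269; adjusted p = 0.639 with an estimated correlation). This last call was lost without siCtrl culture 1 (0.069) or siGRHL2C culture 1 (0.0897). Interferon genes (4 of 36 higher, 2 adjusted over the list alone; camera adjusted p = 0.15) passed without siGRHL2A culture 2 (0.0459), siGRHL2A culture 3 (0.0277) or siGRHL2C culture 3 (0.0145), all with the preset correlation. With all cultures this list had adjusted p = 0.889 with an estimated correlation. The median and the test differed in sign for the uncalled fibroblast list (-0.36, upward), secretory list (-0.09, upward), TGF-beta list (0.08, downward) and epithelial regulator list (0.03, downward).

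CARNMT1, a carnosine methyltransferase, measured 30.4 ± 0.622 CPM with siCtrl, 44.5 ± 3.09 with siGRHL2A and 6.76 ± 1.31 with siGRHL2C, a difference of 2.71 between the GRHL2 siRNAs (adjusted p = 2.45e-06). BLOC1S6 (2.34), the prolactin receptor gene PRLR (2.31) and the matrix gene EFEMP1 (2.16) were also higher with siGRHL2A, and all 4 carried a 7-mer of siGRHL2C, PRLR those of all 3 siRNAs. RP11-73M18.2, at 5.87, 12.4 and 3.10 CPM in the 3 groups, differed by 2.00 (adjusted p = 0.0393). Its call was lost without siCtrl culture 2 (0.0565), siCtrl culture 3 (0.0575), siGRHL2A culture 1 (0.0815), siGRHL2A culture 2 (0.0828), siGRHL2A culture 3 (0.0802) or siGRHL2C culture 3 (0.119). Higher with siGRHL2C were IGHE (-2.81), the aldo-keto reductase AKR1B10 (-2.69), the squamous marker S100A7 (-2.63), KRT17 (-2.47) and BPIFB1 (-2.26), none of them with a 7-mer of any of the siRNAs. KRT17 measured 1.81 ± 0.401 CPM with siCtrl, 4.51 ± 1.07 with siGRHL2A and 24.9 ± 2.77 with siGRHL2C. S100A7 lost its call without siGRHL2A culture 2 (0.0844), siGRHL2A culture 3 (0.0817) or siGRHL2C culture 1 (0.0898), and BPIFB1 without siGRHL2A culture 3 (0.054). Without siGRHL2C culture 1 the contrast RP11-73M18.2 siGRHL2A vs siGRHL2C was larger (3.06), S100A7 siGRHL2A vs siGRHL2C smaller (-1.64) and BPIFB1 siGRHL2A vs siGRHL2C smaller (-1.30). IGHE, AKR1B10 and S100A7 have close paralogs with which reads can be shared.

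Transcripts were compared to ask whether targets of ESRP1, a regulator of epithelial splicing that fell with both GRHL2 siRNAs, were used differently. A minor GRHL2 transcript nearly vanished, CD44 shifted towards a minor transcript, and few other known ESRP targets changed. GRHL2-202 (ENST00000395927) made up 7.38% ± 0.402 of GRHL2 counts with siCtrl, 1.31% ± 0.321 with siGRHL2A and 0.641% ± 0.293 with siGRHL2C, from 578 to 739, 69 to 86 and 12 to 20 counts per culture. Its level fell by 2.96 with siGRHL2A and 5.39 with siGRHL2C on the log2 scale (adjusted p = 0.000299 and 3.31e-05). The main transcript GRHL2-201 (ENST00000251808) measured 268 ± 7.47, 205 ± 10.3 and 82.3 ± 14.6 CPM, with a change of -0.39 with siGRHL2A that missed the threshold (adjusted p = 0.07) and of -1.70 with siGRHL2C (adjusted p = 9.52e-05). CD44-209 (ENST00000433892), a transcript of the hyaluronan receptor, went from 0.975% ± 0.303 of CD44 counts to 6.12% ± 3.33 and 19.4% ± 0.403 (mean change in level 3.15, adjusted p = 0.00447). CD44-201 (ENST00000263398) held 37.5%, 32.7% and 33.2% and did not change in level (-0.41, adjusted p = 0.564, or 0.00807 with the replicate block and 0.0162 without the cultures numbered 1). MAP3K7-204 (ENST00000369329), of the kinase TAK1, made up 56.9% ± 10.1 of MAP3K7 counts, then 87.8% ± 6.01 and 81.3% ± 1.92 (change in level 0.81, adjusted p = 0.00259), and MAP3K7-205 (ENST00000369332) held 34.5% ± 9.83, 2.95% ± 4.81 and 10.9% ± 0.763. The level of MAP3K7-205 itself did not pass (-2.35, adjusted p = 0.136), except without siGRHL2A culture 3 (-4.38, adjusted p = 0.00133).

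Of 43874 transcripts tested 6703 changed in the mean of both siRNAs, 3221 higher and 3482 lower, and without siCtrl culture 3 the count was 4220. Relative transcript use changed in 227 of 9423 genes (885 at an unadjusted p under 0.05), of which 81 did not change in total level. Among the 18 fixed ESRP targets 17 had at least 2 transcripts tested and 3 changed in use, GRHL2 (adjusted p = 2.28e-07), CD44 (0.000286) and MAP3K7 (0.0435). GRHL2 is the target of the siRNAs, so its change in use is no readout of ESRP1. Which exons the CD44 transcripts hold was not examined. Whether the CD44 shift runs in the direction of lower ESRP1 was therefore not tested, and it is no evidence of lost ESRP1 activity. Adjusted over the list alone there were 4, with MAGI1 (0.0205) added. The MAP3K7 call was lost without siCtrl culture 1 (0.0926), 2 (0.284) or 3 (0.245), siGRHL2A culture 1 (0.0969), or siGRHL2C culture 1 (0.0886), 2 (0.153) or 3 (0.117), and with limma (0.0691), which called GRHL2 (0.00147) and CD44 (0.0276). The test of use also called 34 to 48 genes in simulated data without any change, so single genes near the threshold are uncertain.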

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

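The predictions weighed here were written before their tests were run. Those on a graded response took as given that siGRHL2A lowers GRHL2 less than siGRHL2C, which is itself a result of these data. The fits without the cultures numbered 1 and on genes without siRNA 7-mers were added after results were seen.

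Off-target binding of siGRHL2C through its seed could explain part of the genes lower with siGRHL2C than with the other siRNAs: the 7-mer ATATGTA in 3′ UTRs had the most negative t, -15.97, against a most positive t of 7.93 for the siCtrl 7-mer GCAGTAC, and it occurs in the GRHL2 mRNA, as 25.3% of all 7-mers do. A response graded with the depth of GRHL2 depletion was tested on the 2152 genes called lower with siGRHL2C than with siGRHL2A. It predicted that at least 90% of them would also be lower with siGRHL2A than with siCtrl, and 42.6% were (95% interval 40.5 to 44.7). Of the 2152 genes 665 were called higher with siGRHL2A than with siCtrl, an order that a graded response does not give. This set was picked for higher levels with siGRHL2A and need not be lower with siGRHL2C than with siCtrl. The share therefore does not decide how far a graded response accounts for genes lower with siGRHL2C than with the other siRNAs. A steep threshold of GRHL2 could still apply to the genes not called with siGRHL2A. The G2/M shift was not confined to genes with a 7-mer, with a median of 0.9 in those without. Genes of that list change together (estimated correlation 0.784), so this split cannot tell an indirect off-target effect from one of GRHL2.

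Among genes lower with siGRHL2A than with the other siRNAs the leading 7-mer, TGTGTTA, had t = -11.31. The most positive t, 10.82, belonged to GCAGTAC, the leading 7-mer of siCtrl, which is part of the comparator here. TGTGTTA does not occur in the GRHL2 mRNA, although the overlapping runner-up ATGTGTT (t = -10.71) does. The siGRHL2C pair was split in the same way, with ATATGTA present in the GRHL2 mRNA and its runner-up TATGTAA absent. The absence of TGTGTTA therefore does not set siGRHL2A apart from siGRHL2C, and a seed effect of siGRHL2A was left open. A response graded with GRHL2 would not put a gene lowest with siGRHL2A, and 754 genes were called lower than with both siCtrl and siGRHL2C. Since that count follows from how the pattern is defined, it says nothing of their cause.

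Genes higher with both GRHL2 siRNAs than with siCtrl may in part reflect off-target repression by the control siRNA, which would make its targets look induced. GCAGTAC had t = -14.05 for siCtrl against a most positive t of 8.72 for the siGRHL2C 7-mer ATATGTA. CHPF, YWHAH, PXYLP1 and DSP carried a 7-mer of siCtrl, but these 7-mers were picked from the same fold changes, so carrying them is no separate evidence. In the 1725 genes without it the median siGRHL2C minus siGRHL2A change was 0.045 (0.036 to 0.061 when genes were resampled). That interval leaves out the spread between cultures. Scaling alone moved the median siGRHL2A minus siGRHL2C change of all genes from -0.006 (TMM) to -0.039 (upper quartile). In the siGRHL2C minus siGRHL2A direction used here that is an upward shift, close in size to the 0.045. A graded response to GRHL2 was therefore left open.

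The remaining results differ between siGRHL2A and siGRHL2C, and their causes were not tested apart from the patterns above. GRHL2 was higher with siGRHL2A by 1.33. Basal and myoepithelial markers had a median difference of -0.79. Mesenchymal and EMT markers had -0.46. Oestrogen receptor targets had -0.23. G1/S and replication genes had 0.61. G2/M and mitosis genes had 0.91. For p53 targets and apoptosis genes it was -0.33. For cholesterol and fatty acid synthesis genes it was -0.11. For ribosomal protein genes it was -0.17. The 10 splits of the 6 cultures are too few for a share under 0.05 in this contrast, with 4010 genes in the real split (1 of 10) and 0 as the highest other.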

How the results depend on the processing

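Each alternative fixed before the data were examined was run on the results it was fixed for. Normalization other than RLE, other filters, single technical libraries, DESeq2 and limma were not run for the list tests, and other normalizations, single technical libraries and other thresholds were not run for transcripts. The fits without the cultures numbered 1, on genes without siRNA 7-mers, and the limma usage test were chosen after results were seen. Fits without the cultures numbered 1 keep only cultures 2 and 3, which lay closer together, so they may understate the spread. A count within 1.5 times the main count was taken as the same. On that scale 238 settings of the main results gave the same, 27 moved, 3 were weaker and 0 reversed. Except where stated, the cause of a change was not tested.

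Between siGRHL2A and siGRHL2C 4162 genes differed. The count was 6621 with 18 libraries taken as independent, which understates the spread by construction. It was 6333 with the replicate block, 6363 without the cultures numbered 1, 2291 at an adjusted p under 0.01, 61 when tested against a log2 fold change of 1, and 1930 of 7697 genes (25.1%) with no siRNA 7-mer. That last setting tests fewer genes by construction and also gave 3142 for siGRHL2A (40.8%), 3744 for siGRHL2C (48.6%), 3745 for the mean (48.7%) and 2212 for both siRNAs.

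Stricter thresholds lower counts by construction. At an adjusted p under 0.01 siGRHL2A gave 3845 and both siRNAs 2670. Against a log2 fold change of 1 the counts were 233 for siGRHL2A, 525 for siGRHL2C, 335 for the mean and 150 for both. In that test GRHL2 kept its mean change of -1.123 and its siGRHL2A change of -0.459, neither called. With 6 knockdown against 3 control cultures its mean change was -0.976 (adjusted p = 0.0579), since the difference between the siRNAs then enters the residual.

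List tests with an estimated correlation called 0 lists in each contrast, against 2 with siGRHL2A, 8 with siGRHL2C, 4 in the mean and 8 between the siRNAs. Fry called 6, 16 and 10 in the first 3. The replicate block gave 13 with siGRHL2C, and genes without 7-mers gave 4 with siGRHL2A. The block changed no call of a named item other than those given in the report. Within the 1.5 times, it raised the counts to 7861 for siGRHL2A, 8760 for siGRHL2C, 8754 for the mean, 5609 for both siRNAs and 7710 for transcripts. With 6 knockdown against 3 control cultures 5009 genes changed.

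With each culture left out in turn, counts ranged from 4666 to 6314 for siGRHL2A, 6043 to 7266 for siGRHL2C, 5722 to 6978 for the mean, 3139 to 4791 between the siRNAs and 3304 to 4107 for both. Transcripts ranged from 4220 (without siCtrl culture 3) to 5914 and genes changed in use from 158 to 246. GRHL2 ranged from -1.187 to -1.067 in the mean, -0.492 to -0.419 with siGRHL2A and -1.916 to -1.669 with siGRHL2C. Lists called ranged from 2 to 4 with siGRHL2A (4 without siCtrl culture 1), 6 to 9 with siGRHL2C, 3 to 5 in the mean and 7 to 9 between the siRNAs.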

Other observations

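The genes in this part were picked after their values were seen, and the limma usage test and the fits on genes without 7-mers were added after results were seen.

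Several members of the fixed lists told the siRNAs apart. CDKN1A, the cell cycle inhibitor p21, fell with siGRHL2A and rose with siGRHL2C (259, 162 and 641 CPM; log2 fold changes -0.68 and 1.31), and the stress cytokine GDF15 stood at 84.4, 158 and 663 CPM. MKI67, a proliferation marker, measured 540, 689 and 299 CPM and differed by 1.20 between the siRNAs. HMGCS1, the entry enzyme of sterol synthesis, measured 142, 151 and 54.0 CPM, fell with siGRHL2C (-1.39) and differed by 1.48 in the direct test. The collagen gene COL5A1 rose from 9.26 to 16.9 and 48.8 CPM.

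Other members changed in the same direction with both siRNAs, some by different amounts. The oestrogen-induced trefoil genes TFF1 (267, 413 and 699 CPM) and TFF3 (89.4, 223 and 247 CPM) rose, although neither camera nor fry called the oestrogen receptor targets in the mean. The junction gene CGN fell from 248 to 171 and 78.8 CPM while CDH1, which encodes E-cadherin, rose from 956 to 1077 and 1418 CPM, and both differed between the siRNAs (1.12 and -0.40). Lactate dehydrogenase LDHA rose from 364 to 628 and 588 CPM, BNIP3 rose from 87.8 to 158 and 157 CPM, and ADM fell from 42.0 to 16.6 and 20.7 CPM within the same hypoxia list. In the interferon list USP18, a negative regulator of the response, measured 19.8, 15.0 and 4.97 CPM and fell in the mean.

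Relative transcript use changed most clearly in ILF3 (adjusted p = 5.59e-16), LMNA (5.31e-12), DIDO1 (8.24e-12) and PCBP2 (2.43e-11), and in the cytoskeletal genes DST (7.55e-09), SYNE2 (7.78e-09) and MYH14 (1.36e-08). The limma test called 196 genes against 227 with edgeR, and 81 were shared (35.7%). The real grouping gave the most genes changed in use of 30 arrangements of the cultures (1 of 30), with 134 as the highest other. For transcripts it gave the most too (1 of 30, 6703 against 3838 in the highest other). The arrangements ignored that cultures numbered 1 stood apart, and only 8 put 1 culture of each number in each group. Among those 8 the highest others were 31 genes and 0 transcripts. So few cannot give a share under 0.05, so a chance arrangement was not excluded.

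For the mean of both siRNAs the real grouping gave the most genes as well (1 of 100 arrangements, 7032 genes against 5975 in the highest other). The highest other kept each group whole and swapped their roles, and the highest that mixed groups gave 5049. Only 15 of these arrangements put 1 culture of each number in each group, too few for a share under 0.05. A chance arrangement was therefore not excluded here either. For siGRHL2A and siGRHL2C alone the 10 splits are too few for a share under 0.05, with 5704 and 6727 genes in the real split (1 of 10) and 0 as the highest other in both.

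Among genes with none of the siRNA 7-mers, lists outside the main calls passed with the preset correlation. Luminal transcription factors passed with siGRHL2A (adjusted p = 0.00273) and siGRHL2C (0.00183), mesenchymal genes with siGRHL2A (0.0247), and cholesterol synthesis and growth factor receptors with siGRHL2C (both 0.0343). Mesenchymal genes had a median of 0.65 in 12 members without 7-mers and -0.18 in 14 with them. The estimated correlation was not run on this set, and over all genes the luminal list had 0.962 and 0.553 with it, the mesenchymal list 0.962 with siGRHL2A, and cholesterol synthesis and growth factor receptors 0.582 and 0.553 with siGRHL2C, so these calls do not show a masked rise. The 7-mers were also picked from the same fold changes, so the choice of this set is not independent of these calls. All 3 siRNAs had a leading 7-mer past the bound, with t of -14.05, -11.31 and -15.97, and another GRHL2 siRNA or a rescue with siRNA-resistant GRHL2 would separate these effects.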
